A study of Mus musculus with 16 samples.

How the data were processed

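Total RNA of the sorted macrophages was extracted with TRIzol and made into libraries with a VAHTS RNA-seq kit, per the labels' protocols. The submitters' processing notes name fastp, HISAT, HTSeq and the build mm10, without tool versions. The annotation and the formula behind the values are not given in the sources used here. The deposited table is called FPKM in its name, a unit scaled to gene length and library size that is not a count; how the authors computed it is not stated.

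Samples were assigned to 4 groups of 4 by the treatment label. Nothing in the labels says that the samples of a group came from separate animals. Each column name was then compared with the title and description of every sample, ignoring case and punctuation, and a match was accepted where one text contained the other for 1 sample only. All 15 value columns remained unmatched, and no measured value from them was used in any step. The moderated log-scale tests and list tests planned before the data were examined were therefore not run, and no leave-one-out fits were made. A planned check of how far the treated groups' differences from IgG resemble each other, against simulated unchanged groups, was not run either.

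Only the gene names were analysed. Of the 26931 names, 20929 (77.7%) were gene names of GENCODE M21 and 25977 (96.5%) were symbols of the RefSeq annotation of GRCm38.p6. Coordinates were taken from GENCODE M21, whose assembly GRCm38 is mm10. Members of the fixed lists were looked up by current symbol, and again with the synonyms that RefSeq records.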

Results

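RNA-seq was used to profile macrophages taken from mouse liver cancer by magnetic sorting on the product of Adgre1, a surface protein of mouse macrophages. The 16 samples formed 4 treatment groups of 4 samples each. One group received control IgG, one an antibody against PD-1, one an antibody against CX3CR1, and one both antibodies. PD-1, encoded by Pdcd1, is an inhibitory receptor best known on activated T cells. CX3CR1, encoded by Cx3cr1, is the receptor for the chemokine CX3CL1 and is expressed by monocytes and subsets of macrophages. The title of the series names a benefit of combining the antibodies as its subject, so the design implies comparing each treated group with IgG, the combination with each single antibody, and the effect of anti-CX3CR1 with and without anti-PD-1.

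No expression level, fold change or test is reported for any of these comparisons. The expression table held 15 value columns for the 16 samples. The sample titles carried the prefix TAM, the treatment and a replicate number. The column headers instead joined the same prefix to numbers from 1 to 16, in which only the number 2 was skipped. The highest number equalled the number of samples, but no label numbered the samples in this way or said which sample the skipped number stood for. Of the 15 columns, 0 could be matched by name to a single sample, and no label paired the column numbers with treatments. The order of the columns and the values in them were not used to assign treatments, because groups formed in that way would be assumed and not known. Direction, size and error of any treatment effect therefore remain undetermined here. The depth of each library is undetermined too, since values scaled to library size would not give it even with matched columns.

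The gene names of the table, which do not depend on the assignment of columns, were examined. The table listed 26931 genes, each name once. All 7 genes chosen by name before the data were examined were listed. Adgre1, Cx3cr1 and Pdcd1 encode the sorting marker and the antibody targets, and Cx3cl1 and Cd274 encode ligands of those targets. Il27 and Ptgs2 were added as genes of macrophage function that the labels do not mention. Cx3cr1 lies on chromosome 9 from 119901616 to 120069879 on the minus strand, and Cx3cl1 on chromosome 8 from 94772009 to 94782427 on the plus strand. Pdcd1 lies on chromosome 1 from 94038305 to 94052553 on the minus strand, and Cd274, which encodes PD-L1, on chromosome 19 from 29367455 to 29388095 on the plus strand. Adgre1 lies on chromosome 17 from 57358691 to 57483527 on the plus strand. Il27, which encodes a subunit of the cytokine IL-27, lies on chromosome 7 from 126589010 to 126594941 on the minus strand, and Ptgs2, which encodes an enzyme of prostaglandin synthesis, on chromosome 1 from 150100031 to 150108227 on the plus strand. All coordinates are the full extents of the gene entries of GENCODE M21 on GRCm38 (mm10), where each of these genes is annotated as protein coding. The extents in the annotation behind the deposited values, which is not given, may differ.

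Marker and pathway lists had been fixed before the data were examined. They comprised 38 lists with 544 different genes, of which 531 were found among the gene names of the table used here and 13 were not. Only the names were looked up, and the expression of none of these genes was analysed. The lists for macrophage core genes, Kupffer cells, monocytes and lipid-associated macrophages were complete, with 12, 14, 15 and 12 members. The lists for classical activation, with 16 genes, for alternative activation, with 17 genes, and for the interferon gamma response, with 18 genes, were complete as well. In total 34 lists were complete. The type I interferon list had 17 of 19 members, without Mx1 and Mx2. The T cell list had 14 of 17 members, the B cell list 10 of 13 and the plasma cell list 6 of 11, and the genes they lacked were constant regions of the T cell receptor and of immunoglobulins. A gene being listed says nothing about its expression in these cells.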

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

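The alternatives below were chosen after seeing the data. Requiring a column name to equal a sample's title or description matched 0 of the 15 columns to a single sample. That rule is stricter than the main rule, so it could not match a column that the main rule left without any match. Using only the number at the end of the title matched 0 columns to a single sample too. Of the columns, 3 shared their number with 4 samples each, 1 from every group, and the other 12 shared it with none. Because every group uses the same replicate numbers, that rule could not single out a sample. Neither result is therefore a test of the failed match. Adding synonyms to the lookup of list members left the number listed in the table at 531 of 544. No paired analysis was possible because 0 of the 15 columns could be matched to a single sample. Even with matched columns, a replicate number shared between groups would not by itself show that those samples were paired. Changes of pseudocount, low-value filter, scaling, weights, variance prior, threshold and replicates left out were not run, for want of any value that could be assigned to a group.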
